A study of Canis lupus familiaris with 18 samples.

How the data were processed

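Messenger RNA abundance was measured by RNA sequencing in corpora lutea of 18 bitches, 3 on each of 6 days that ran from day 10 to day 60 after ovulation in steps of 10 days. Each library came from its own animal, so the p-values measure the spread between animals. Samples were grouped by the day in their labels and are named here by day and replicate. No paired analysis was possible because each bitch was sampled on 1 day and the replicate numbers only name samples.

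The deposited table held 1 column of FPKM per animal, a fragment count scaled by the authors for gene length and library size. CASAVA 1.8.2, TopHat2 2.0.9 and Cufflinks are named per the submitters' processing notes, without their roles or options. The genome build and the annotation release are not given in the sources used here, and coordinates are those of the deposited table. Read counts are not given in the table, so the sequencing depth is unknown and no interval or detection floor was computed. Upper quartiles of FPKM were close between libraries (5.81 to 6.4) while the sums ranged from 493168 to 1259018, and whether the values were scaled beyond the fragment total is not stated.

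The table had 34408 entries, of which 9063 carried no gene name, 16247 carried a single gene symbol, 979 named several genes and 5397 were at 0 in all libraries. Entries with an FPKM of at least 1 in at least 3 samples were tested. These were 17147 entries, with a single gene symbol for 11715, no gene name for 2981, and an Ensembl identifier, several genes or a small RNA for 2451. Entries with the same symbol were tested separately, and the entry with the highest mean stood for the symbol in gene lists and among named genes.

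Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1, with an intensity trend in the empirical Bayes step and 1 model of 6 day means (12 residual degrees of freedom). The tests were a moderated F test over the days, a linear and a quadratic trend over equally spaced days, day 60 against day 10, and the 5 consecutive comparisons. Tests were two-sided, with Benjamini-Hochberg adjustment over the entries and a threshold of 0.05 on the adjusted p. A linear change is the fitted change from day 10 to day 60 on the log2 scale. A positive quadratic value marks a course that bent upward (a trough, or a fall that levelled off) and a negative value a course that bent downward (a peak, or a rise that levelled off, or a fall that steepened). All changes are on the log2(FPKM + 1) scale, which understates fold changes of genes with low FPKM. Consecutive comparisons share a day, so their results were not set against each other.

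A total of 34 gene lists (842 genes, of which 689 were found and 590 were tested) covered steroid and cholesterol metabolism, hormone receptors, prostaglandins, growth factors, vessels, matrix, immune and other cell types, cell cycle, organelles, stress responses and ribosomal proteins. Each list was tested in 8 comparisons with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 272 pairs of list and comparison. Camera with an estimated correlation and limma's fry were run beside it. Fry's p tests whether the genes of a list move on balance 1 way, and its mixed p whether they change in either direction, and neither compares a list with other genes. Older gene names were matched through a RefSeq gene table for the assembly UU_Cfam_GSD_1.0, which also gave a chromosome for 579 tested list genes; for 7 of them it differed from that of the deposited entry.

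Genes are named by the following rule. A set of genes of luteal function is named whether or not it passed. For the linear trend and for day 60 against day 10, the 10 genes with the largest change in each direction follow, among those with a gene symbol, an adjusted p under 0.05 and a mean of at least 5 FPKM on their highest day. For day 60 against day 10 the groups also had to be free of overlap. For the quadratic trend and each consecutive comparison, 5 genes in each direction follow by the same rule. For each list, up to 4 members with the smallest p among those that passed are named, or up to 2 where none passed. Some genes that meet this rule are not described here. The comparisons, tests, filter, lists, naming rule and first group of other settings were chosen before the data were examined.

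That first group of settings was a pseudocount of 0.1 FPKM, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, array weights, fits of only the 6 samples compared, and leaving out each library in turn. A division of the libraries into 6 and 12 was seen in the values, so settings chosen after seeing the data added a term for it and a fit of the 12 libraries alone. Others added then left out entries listed at 0 beside a median of 10 FPKM or more, kept only entries with a single symbol, summed entries of 1 symbol, left out day 50 replicate 2 in the list tests, and left out list members on another chromosome. Medians of all tested entries moved by less than 0.1 under every scaling.

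The procedure was tested on simulated data of 17147 genes with 200 changed genes. At a log2 change of 1 it recovered 33% of the changed genes with the F test, 59% with the linear trend, 76% with the quadratic trend, 40% for day 60 against day 10, and between 35% and 48% in the consecutive comparisons. At a log2 change of 2 the share was between 83% and 95%, and no call had the wrong sign. A simulated rise of the cell cycle list between day 10 and day 20 gave an adjusted p of 2.79e-57, and 0 other lists were called. The 200 changed genes were drawn from those with higher mean values. The simulated noise was independent between genes, so it could not test whether camera's preset correlation suits these data.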

Results

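Gene expression was followed in the canine corpus luteum from day 10 to day 60 after ovulation, with 3 bitches on each of 6 days. The corpus luteum makes progesterone over this whole period, and the genes of steroid output, cholesterol supply, vessels, matrix and immune cells were read for their course. Of the 17147 entries tested, 2983 differed between the days by the moderated F test of limma, and 2222 of these carried a single gene symbol. Among those 2222 genes the highest mean fell on day 10 for 934, on day 20 for 334, on day 30 for 219, on day 40 for 81, on day 50 for 188 and on day 60 for 466. A linear trend was called for 5538 entries, with 2507 rising and 3031 falling, and 2420 of them changed at least 2-fold. Libraries of the same day had a median correlation between 0.883 and 0.961.

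**Figure D1:**
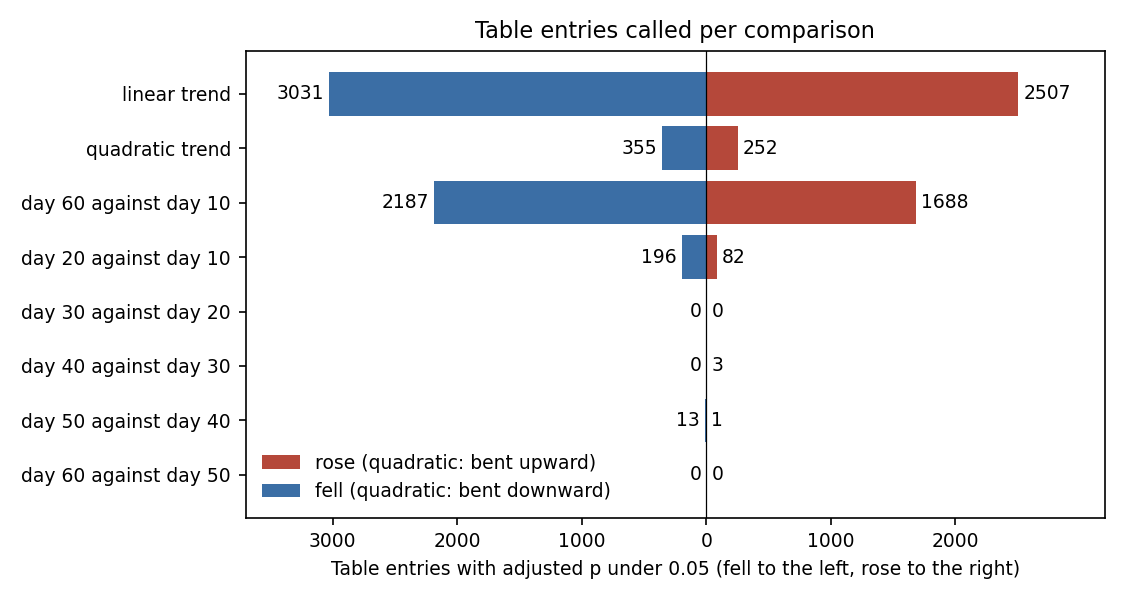
Table entries called at an adjusted p under 0.05 in each comparison, split into those that rose and those that fell (bent upward or downward for the quadratic trend). The horizontal axis gives the number of entries, from 5538 for the linear trend to 0 for day 30 against day 20.

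The gene of the 3-beta-hydroxysteroid dehydrogenase that makes progesterone (HSD3B, chromosome 17, 56552944 to 56561064) fell from 3372 ± 52.3 FPKM on day 10 to 100.3 ± 85.4 on day 60 (mean ± SD, n = 3 each). Its fitted log2 change was -5.76 (SE 0.36, adjusted p = 7.47e-08). CYP11A1, whose enzyme cleaves the cholesterol side chain (chromosome 30, 37367814 to 37495371), fell less, with a log2 change of -1.31 (SE 0.33, adjusted p = 0.00719; 0.0728 in the 12 libraries described below). Its redox partner FDX1 fell by 1.51 (adjusted p = 0.0014) and the transcription factor gene GATA6 by 0.96 (adjusted p = 0.000449). STAR, whose protein carries cholesterol into mitochondria (chromosome 16, 27325825 to 27410162), was listed at 0 in all 9 libraries of days 10, 20 and 30. It stood at 3477, 3626 and 2964 FPKM on day 40, at 499.5, 2006 and 2442 on day 50, and at 1387, 1342 and 1001 on day 60. The zeros may be a failed estimate, because a merged entry of ASH2L and EIF4EBP1 with the same coordinates was at 0 in the same 9 libraries. The aromatase gene CYP19A1 (chromosome 30, 16950769 to 16989250) rose by 1.36 (SE 0.28, adjusted p = 0.00206), from 114 ± 33.6 FPKM on day 10 to 395 ± 53.9 on day 60.

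**Figure D2:**
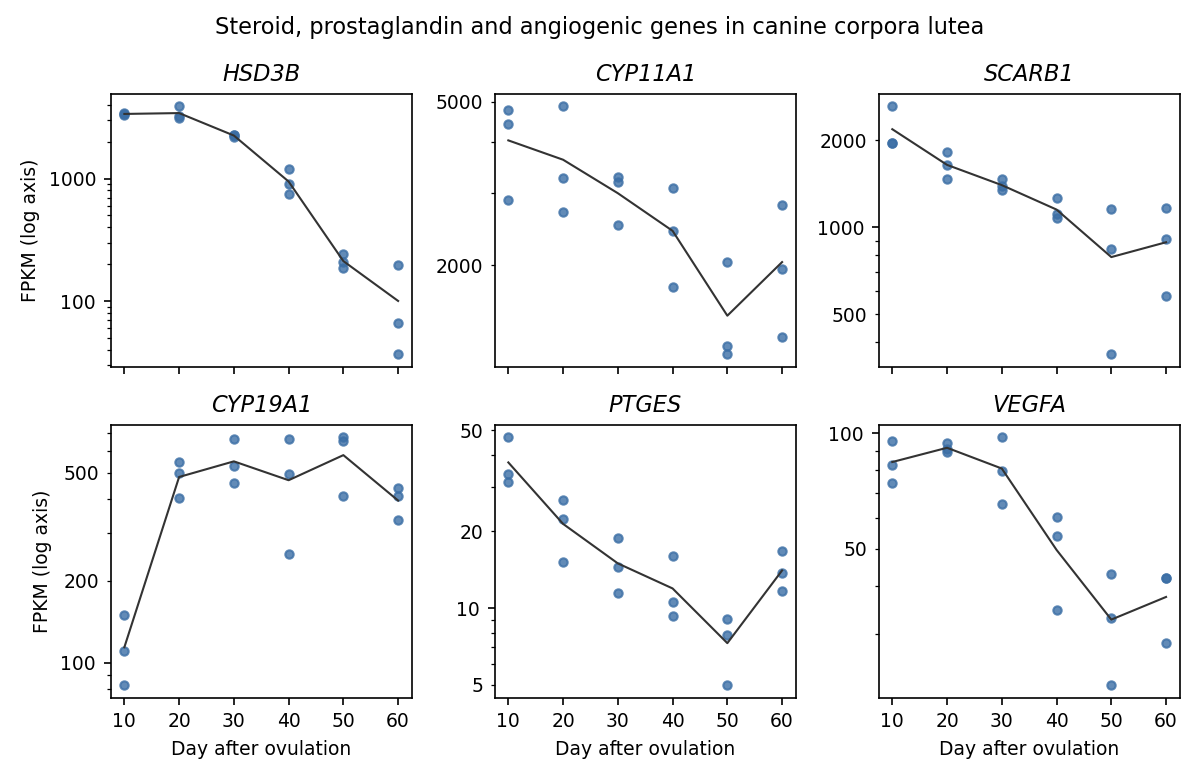
FPKM on a log axis against day after ovulation for HSD3B, CYP11A1, SCARB1, CYP19A1, PTGES and VEGFA. Points are libraries and lines join day means, with HSD3B at 3372 on day 10 and 100.3 on day 60.

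Of the 11 genes of progesterone synthesis, 1 rose and 6 fell (2 and 6 adjusted over the list alone). The gene that rose was STAR, whose rise rests on zeros that may be a failed estimate. The list's median log2 change was -0.68 while its mean was 0.26, the mean being set by STAR, and camera put the list down (adjusted p = 0.313). Of the 8 genes of androgen and estrogen synthesis, 2 rose and 4 fell (2 and 4 adjusted over the list alone), with a median of -0.45 (adjusted p = 0.207). HSD17B12, a fatty acid elongation and steroid dehydrogenase gene, fell by 1.69 (adjusted p = 1.14e-06). HSD17B7 of estradiol and sterol synthesis fell by 2.21 (adjusted p = 0.00013) and the steroid sulfatase gene STS by 1.04 (adjusted p = 0.00082). CYP11A1, HSD3B and CYP19A1 kept their direction within the 6 libraries described below (-1.41, -5.89 and 0.87) and within the other 12 (-1.27, -5.69 and 1.60).

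Most genes of cholesterol synthesis fell, and 17 of 20 passed with 0 rising (18 adjusted over the list alone). SQLE (chromosome 13, 22992598 to 23018133), which makes the squalene epoxide, fell from 119.9 ± 38.4 to 6.36 ± 2.39 FPKM (log2 change -4.75, SE 0.34, adjusted p = 2.42e-07). LSS (chromosome 31, 39475423 to 39778769), which turns the squalene epoxide into the first sterol, fell by 4.08 (SE 0.33, adjusted p = 6.32e-07). IDI1 (chromosome 2, 33927242 to 33930720), the isopentenyl isomerase gene, fell by 3.70 (SE 0.29, adjusted p = 5.36e-07). The list's median log2 change was -2.77 and its camera adjusted p was 9.15e-14 (adjusted p = 0.246 with an estimated correlation).

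**Figure D3:**
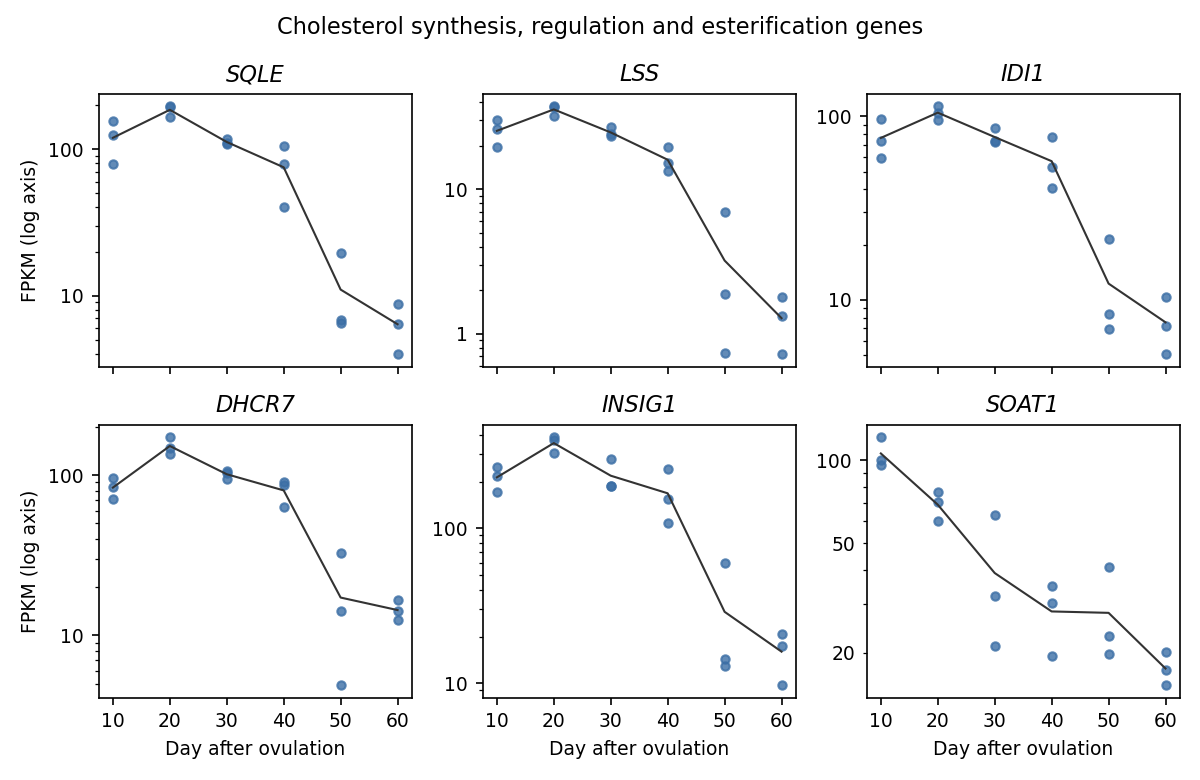
FPKM on a log axis against day after ovulation for SQLE, LSS, IDI1, DHCR7, INSIG1 and SOAT1. Points are libraries and lines join day means, with SQLE at 75.3 on day 40 and 10.98 on day 50.

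Some genes of cholesterol uptake and storage also fell. The high-density lipoprotein receptor gene SCARB1 (chromosome 26, 5020780 to 5127380) fell by 1.52 (SE 0.32, adjusted p = 0.00201; 0.0541 in the 12 libraries). SOAT1, which stores cholesterol as ester, fell by 2.43 (adjusted p = 1.97e-05). The lipoprotein receptor gene LRP8 fell by 2.33 (adjusted p = 0.000157) and the sterol sensor gene NR1H3 by 0.74 (adjusted p = 0.00145). Of the 18 genes of cholesterol uptake, storage and efflux, 2 rose and 9 fell (3 and 9 adjusted over the list alone), with a median of -0.49 (adjusted p = 0.017; adjusted p = 0.25 with an estimated correlation).

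Some prostaglandin genes fell, among them the inducible cyclooxygenase gene PTGS2, listed as COX-2 (chromosome 7, 19668010 to 19674918), going from 11.9 ± 3.12 FPKM on day 10 to 0.202 ± 0.102 on day 60. Its log2 change was -3.14 (SE 0.32, adjusted p = 5.15e-06). The prostaglandin E synthase gene PTGES (chromosome 9, 54036502 to 54267415) fell by 1.62 (SE 0.23, adjusted p = 0.000102). The prostacyclin synthase gene PTGIS fell by 1.86 (adjusted p = 4.77e-06) and the prostaglandin carrier gene SLCO2A1 by 3.02 (adjusted p = 6.39e-06). The receptor gene PTGFR did not pass (-0.29, adjusted p = 0.366). Of 13 prostaglandin genes 0 rose and 5 fell (5 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.0142; adjusted p = 0.246 with an estimated correlation).

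Few hormone receptor genes passed. The luteinizing hormone receptor gene LHCGR (0.02, adjusted p = 0.948), the prolactin receptor gene PRLR (-0.52, adjusted p = 0.118), the estrogen receptor gene ESR2 (-0.31, adjusted p = 0.258) and the insulin receptor gene INSR (-0.11, adjusted p = 0.758) did not pass. ESR1 was not tested because its highest value was 1.1 FPKM. The progesterone receptor gene PGR fell by 0.61 (SE 0.18, adjusted p = 0.0166), and did not pass without day 10 replicate 1 (0.0559) or without day 60 replicate 3 (0.053). PGRMC2, of the membrane progesterone binding family, rose by 0.77 (adjusted p = 0.0134; 0.0843 in the 12 libraries). Of 12 hormone receptor genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), with a median of -0.21 (adjusted p = 0.699).

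Genes of insulin-like growth factor signalling fell in part. IGF1 (chromosome 15, 41195964 to 41275960) fell by 1.12 (SE 0.21, adjusted p = 0.00102). PAPPA, whose protease frees the factor from its binding proteins, fell by 3.74 (adjusted p = 5.01e-09). The binding protein gene IGFBP4 fell by 1.62 (adjusted p = 3.31e-05), while IGFBP6 rose by 2.63 (adjusted p = 1.81e-05), from 7.99 to 53.5 FPKM. Of 20 such genes 1 rose and 8 fell (1 and 8 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.0122; adjusted p = 0.371 with an estimated correlation). Of 21 genes of glycolysis and the hypoxia response, 5 rose and 9 fell (6 and 9 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.362). The oxygen-sensing genes HIF1A (-1.05, SE 0.23, adjusted p = 0.0026) and EPAS1 (-1.87, adjusted p = 8.01e-05) fell, the carbonic anhydrase gene CA9 rose by 3.02 (adjusted p = 2.78e-06), and the glucose transporter gene SLC2A1 did not pass (-0.45, adjusted p = 0.179).

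Most vascular genes fell over the series. VEGFA, which drives vessel growth (chromosome 12, 12207781 to 12225072), fell by 1.58 (SE 0.22, adjusted p = 7.9e-05), from 84.1 ± 10.8 to 37.4 ± 7.85 FPKM. Its receptor genes KDR (chromosome 13, 47438397 to 47644931) and FLT1 fell by 2.17 (SE 0.32, adjusted p = 0.000145) and by 1.75 (SE 0.37, adjusted p = 0.00243; 0.0739 in the 12 libraries). The endothelin receptor gene EDNRB fell by 3.89 (adjusted p = 9.75e-08) and VEGFC by 1.90 (adjusted p = 2.59e-05). Of 28 genes of angiogenic signalling 2 rose and 17 fell (3 and 19 adjusted over the list alone), with a median of -0.76 (adjusted p = 9.92e-05; adjusted p = 0.291 with an estimated correlation). Of 15 endothelial markers 0 rose and 13 fell (14 adjusted over the list alone), with a median of -1.16 (adjusted p = 1.95e-05; adjusted p = 0.311 with an estimated correlation). Among them were the adhesion gene PECAM1 (-1.88, adjusted p = 2.1e-05), VWF of platelet binding (-1.97, adjusted p = 0.000378) and PLVAP of endothelial pores (-2.04, adjusted p = 0.000483). Of 9 pericyte and smooth muscle markers 0 rose and 4 fell (5 adjusted over the list alone), with a median of -0.59 (adjusted p = 0.174), among them NOTCH3 (-1.78, adjusted p = 0.0012).

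Many matrix genes fell as well. The collagenase inhibitor gene TIMP1 (chromosome X, 41179940 to 41241624) fell from 14930 ± 514 to 525 ± 157 FPKM (log2 change -4.69, SE 0.44, adjusted p = 2.84e-06). The fibronectin gene FN1 fell by 3.31 (adjusted p = 8.18e-07), the collagen gene COL3A1 by 2.10 (adjusted p = 0.000123) and SPARC, of collagen assembly, by 1.74 (adjusted p = 0.000217). Of 22 fibroblast and matrix genes 1 rose and 12 fell (2 and 13 adjusted over the list alone), with a median of -0.92 (adjusted p = 0.000309; adjusted p = 0.342 with an estimated correlation). Of 13 basement membrane genes 0 rose and 11 fell (11 adjusted over the list alone), with a median of -1.66 (adjusted p = 4.52e-07; adjusted p = 0.308 with an estimated correlation), among them the collagen gene COL4A1 (-2.53, adjusted p = 3.3e-06) and the nidogen gene NID2 (-2.09, adjusted p = 8.24e-06). Of 17 matrix proteases and inhibitors 0 rose and 9 fell (9 adjusted over the list alone), with a median of -0.89 (adjusted p = 0.00109; adjusted p = 0.307 with an estimated correlation), among them the aggrecanase genes ADAMTS4 (-1.63, adjusted p = 7.99e-05) and ADAMTS5 (-1.44, adjusted p = 0.000302).

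Immune cell markers had calls in both directions. The T cell receptor chain gene CD247 rose by 1.93 (adjusted p = 0.000132), the T cell gene CD5 by 1.86 (adjusted p = 9.78e-06) and the T cell adaptor gene SKAP1 by 1.41 (adjusted p = 0.000146). Of 13 T and natural killer cell markers 5 rose and 0 fell (6 adjusted over the list alone; 9 without day 50 replicate 2), with a median of 0.81 (adjusted p = 0.00226; adjusted p = 0.408 with an estimated correlation). Of 15 macrophage markers 0 rose and 6 fell (7 adjusted over the list alone), with a median of -0.65 (adjusted p = 0.0298; adjusted p = 0.584 with an estimated correlation), among them the perforin-like gene MPEG1 (-1.67, adjusted p = 0.00059). Of 5 B cell markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.887), and the B cell receptor brake CD22 fell by 0.85 (adjusted p = 0.00297). Of 9 neutrophil and mast cell markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.696), and the mast cell chymase gene CMA1 rose by 1.75 (adjusted p = 0.00232). Of 13 antigen presentation genes 3 rose and 0 fell (3 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.418), and CD74, the class II chaperone gene, rose by 1.72 (adjusted p = 0.00192; 0.0757 in the 12 libraries).

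Some signalling genes of inflammation fell. The cytokine genes LIF (-2.39, adjusted p = 2.05e-05) and IL33 (-1.61, adjusted p = 0.000483) fell, and of 26 cytokines and chemokines 1 rose and 6 fell (1 and 6 adjusted over the list alone), with a median of -0.48 (adjusted p = 0.1). CD55, which protects cells from complement (chromosome 7, 6360963 to 6389324), fell by 2.69 (adjusted p = 9.25e-07), the thrombomodulin gene THBD by 1.70 (adjusted p = 0.000112) and the complement gene C3 by 2.48 (adjusted p = 0.000824). Of 17 complement and coagulation genes 1 rose and 7 fell (1 and 9 adjusted over the list alone), with a median of -0.49 (adjusted p = 0.0112; adjusted p = 0.324 with an estimated correlation). Of 25 immediate early and stress genes 1 rose and 11 fell (1 and 11 adjusted over the list alone), with a median of -0.60 (adjusted p = 0.0578), among them the Fos family gene FOSL1 (-1.30, adjusted p = 8.06e-06) and the cytokine brake SOCS3 (-2.04, adjusted p = 0.00181). Of 27 genes of transforming growth factor beta signalling 6 rose and 10 fell (7 and 11 adjusted over the list alone), with a median of -0.10 (adjusted p = 0.342). The bone morphogenetic protein inhibitor gene GREM1 (-3.39, adjusted p = 2.42e-07), the activin-binding gene FSTL3 (-3.94, adjusted p = 1.51e-06) and the inhibin gene INHA (-3.80, adjusted p = 2e-05) fell.

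Most proliferation genes fell, from low levels. The proliferation marker MKI67 fell by 1.31 (SE 0.20, adjusted p = 0.000159), from 1.79 ± 0.386 to 0.131 ± 0.0468 FPKM, the topoisomerase gene TOP2A by 2.16 (adjusted p = 4.82e-06), the ribonucleotide reductase gene RRM2 by 2.20 (adjusted p = 1.87e-05) and the mitotic kinesin gene KIF20A by 1.48 (adjusted p = 6.99e-06). Of 30 cell cycle genes 1 rose and 21 fell (1 and 23 adjusted over the list alone), with a median of -0.92 (adjusted p = 1.22e-08; adjusted p = 0.311 with an estimated correlation). Of 25 apoptosis genes 0 rose and 7 fell (7 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.177), among them the death receptor gene TNFRSF1A (-1.10, adjusted p = 0.0019) and the survival gene MCL1 (-0.79, adjusted p = 0.00377). Of 27 autophagy and lysosome genes 1 rose and 11 fell (2 and 12 adjusted over the list alone), with a median of -0.43 (adjusted p = 0.0489; 0.0545 without day 50 replicate 2; adjusted p = 0.502 with an estimated correlation), among them the progranulin gene GRN (-1.21, adjusted p = 0.000602).

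HADH of fatty acid oxidation (-3.01, adjusted p = 3.89e-08) and CD36 of fatty acid uptake (-1.57, adjusted p = 2.69e-06) fell, and of 21 fatty acid genes 2 rose and 13 fell (3 and 14 adjusted over the list alone), with a median of -0.59 (adjusted p = 0.000741; adjusted p = 0.308 with an estimated correlation). Of 24 oxidative phosphorylation genes 1 rose and 7 fell (1 and 7 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.456), among them the complex I gene NDUFS1 (-1.32, adjusted p = 4.78e-05). Of 25 antioxidant genes 6 rose and 5 fell (6 and 6 adjusted over the list alone), with a median of 0.03 (adjusted p = 0.887). The glutathione transferase gene MGST2 rose by 2.43 (adjusted p = 7.53e-06), while the glutathione synthesis gene GCLC fell by 2.21 (adjusted p = 0.00272). Of 21 genes of the unfolded protein response 3 rose and 11 fell (3 and 12 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.00664; adjusted p = 0.311 with an estimated correlation), among them SEL1L of protein disposal (-1.93, adjusted p = 5.13e-05) and the chaperone gene HSPA5 (-1.56, adjusted p = 0.000844).

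Markers of other tissues and ribosomal protein genes rose in part. The epithelial genes CLDN3 of tight junctions (3.24, adjusted p = 9.94e-07) and EPCAM of cell adhesion (2.77, adjusted p = 6.3e-05) rose. Of 5 epithelial markers 3 rose and 0 fell (4 adjusted over the list alone), with a median of 0.78 (adjusted p = 0.0155; adjusted p = 0.277 with an estimated correlation). Of 12 follicle and oocyte genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 0.74 (adjusted p = 0.122), and FST, which binds activin, rose by 1.39 (adjusted p = 0.0134; 0.0973 in the 12 libraries). Of 6 adipocyte and erythrocyte markers 2 rose and 0 fell (3 and 1 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.364). Of 24 ribosomal protein genes 11 rose and 0 fell (18 adjusted over the list alone; 15 over all genes without day 50 replicate 2), with a median of 1.16 (adjusted p = 6.42e-05; adjusted p = 0.557 with an estimated correlation). The median FPKM of these 24 genes was 1634.2 in day 50 replicate 2, and 960.1, 702.9 and 390.2 in day 60 replicates 1, 2 and 3. For 4 of the 24 the entry lay on another chromosome than the RefSeq gene table gives.

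The largest rises of the linear trend reached beyond these lists. TNN, a tenascin of the extracellular matrix (chromosome 7, 24246057 to 24384080), rose by 6.67 (SE 0.48, adjusted p = 2.67e-07), and the Wnt inhibitor gene NKD2 by 6.29 (adjusted p = 3.7e-07). The regulatory T cell receptor gene TNFRSF18 (chromosome 5, 56394293 to 56397687) rose by 5.98 (SE 0.27, adjusted p = 3.72e-09). The monooxygenase gene FMO2 (6.06, adjusted p = 8.3e-06) rose with OPALIN of myelin (5.08, adjusted p = 8.37e-06). The kallikrein gene KLK1 (5.01, adjusted p = 0.000204), the fatty acid transporter gene SLC27A2 (4.71, adjusted p = 2.42e-07) and the peptidase gene NAALADL1 (4.43, adjusted p = 4.74e-06) also rose. The largest falls were of FABP3, which binds fatty acids (chromosome 2, 69635256 to 69762860; -6.91, SE 0.51, adjusted p = 3.11e-07), and of the carbonic anhydrase gene CA2 (chromosome 29, 31959122 to 31975411; -6.85, SE 0.53, adjusted p = 4.08e-07). They were followed by the oxidase gene HAO2 (-6.04, adjusted p = 5.01e-09), ACSL4 of arachidonic acid activation (chromosome X, 82863804 to 82954063; -5.91, SE 0.29, adjusted p = 5.01e-09), the phospholipase gene PLA2G3 (-5.76, adjusted p = 2.84e-07), RGN of calcium handling (-4.64, adjusted p = 1.14e-06) and the fibrinogen gene FGG (-4.61, adjusted p = 5.68e-05).

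The linear trend was tested with limma in 18 libraries, and 7492 entries had an unadjusted p under 0.05 where 857 are expected by chance. Of the 3922 called entries with a single gene symbol, 1499 rose and 2423 fell. The trend was also fitted within each part of a division of the libraries seen in the values, into 6 libraries (day 10 replicate 2, day 20 replicate 3, day 30 replicate 2, day 40 replicate 1, day 50 replicate 1 and day 60 replicate 2) and the other 12. With a straight line over the days in place of day means, 429 and 3059 entries were called within these parts, and over all tested entries the changes within the 6 and within the 12 correlated at 0.782. Changes within the 6 and within the 12 were -1.63 and -1.46 for SCARB1, -2.51 and -3.45 for PTGS2, -1.88 and -1.49 for PTGES, and -1.62 and -1.56 for VEGFA. They were -2.93 and -1.79 for KDR, -1.94 and -1.65 for FLT1, -0.95 and -1.09 for HIF1A, -1.65 and -0.85 for IGF1, and -1.43 and -1.25 for MKI67. The called gene PGR had -0.17 and -0.83. Among genes without a call the values were -0.42 and -0.57 for PRLR, -0.12 and -0.40 for ESR2, -0.10 and -0.62 for SLC2A1, and of opposite sign for PTGFR (0.16 and -0.52), LHCGR (-0.17 and 0.11) and INSR (-0.46 and 0.07).

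Between day 10 and day 60, TNN rose from 3.55 ± 2.60 to 665 ± 140 FPKM (log2 change 7.32, SE 0.57, adjusted p = 1.19e-06). KLK2, a kallikrein of prostatic fluid (chromosome 1, 105960525 to 106004618), rose by 5.82 (SE 0.83, adjusted p = 0.000183), with 167 ± 116 FPKM on day 10 and 11410 ± 12110 on day 60. TNFRSF18 (5.76, adjusted p = 7.64e-08), NKD2 (6.63, adjusted p = 2.47e-06) and FMO2 (5.63, adjusted p = 0.000133) rose as well. So did KLK1 (5.31, adjusted p = 0.000825), SLC27A2 (5.25, adjusted p = 9.41e-07) and the synaptic vesicle gene SV2B (4.91, adjusted p = 0.000758). CA2 fell from 583 ± 93.5 to 4.60 ± 4.16 FPKM (-6.98, SE 0.62, adjusted p = 3.56e-06) and FABP3 from 1184 ± 389 to 18.7 ± 7.98 (-5.93, adjusted p = 1.13e-05). HAO2 (-5.52, adjusted p = 1.7e-07), ACSL4 (-5.50, adjusted p = 1.7e-07), PLA2G3 (-5.36, adjusted p = 5.44e-06) and TIMP1 (-4.88, adjusted p = 1.89e-05) fell. The thyroxine carrier gene TBG (-4.52, adjusted p = 1.02e-06), FGG (-4.51, adjusted p = 0.000455) and the thioredoxin-like gene TMX4 (-4.50, adjusted p = 1.2e-06) fell too.

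Among the genes of luteal function, HSD3B fell by 5.40 (SE 0.42, adjusted p = 1.2e-06) between day 10 and day 60, while CYP11A1 (-1.02, adjusted p = 0.0752) did not pass. CYP19A1 rose by 1.82 (adjusted p = 0.00135). PTGS2 (-3.40, adjusted p = 2.38e-05), KDR (-2.20, adjusted p = 0.000832), HIF1A (-1.38, adjusted p = 0.00186), IGF1 (-1.77, adjusted p = 0.000172) and MKI67 (-1.30, adjusted p = 0.00107) fell. PTGES (-1.34, adjusted p = 0.00242) and VEGFA (-1.16, adjusted p = 0.00437) fell too, but in the 12 libraries alone their adjusted p were 0.0502 and 0.0906. SCARB1 fell by 1.34 (adjusted p = 0.0174; 0.0728 without day 10 replicate 1, 0.0811 without day 60 replicate 2 and 0.219 in the 12 libraries). FLT1 fell by 1.62 (adjusted p = 0.0158; 0.0564 without day 10 replicate 1, 0.0602 without day 60 replicate 1, 0.053 without day 60 replicate 2 and 0.192 in the 12 libraries). PGR fell by 0.79 (adjusted p = 0.0139; 0.064 without day 10 replicate 1, 0.0636 without day 60 replicate 3 and 0.0551 with only the 6 samples compared). LHCGR (0.03, adjusted p = 0.937), PRLR (-0.59, adjusted p = 0.162), ESR2 (-0.30, adjusted p = 0.391), PTGFR (-0.24, adjusted p = 0.585), SLC2A1 (-0.07, adjusted p = 0.889) and INSR (0.08, adjusted p = 0.875) did not pass.

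By list, 16 of 20 cholesterol synthesis genes fell between day 10 and day 60 and 0 rose (18 adjusted over the list alone), with a median of -2.12 (adjusted p = 2.96e-12; adjusted p = 0.25 with an estimated correlation). Of 30 cell cycle genes 1 rose and 22 fell (1 and 23 adjusted over the list alone; median -0.94, adjusted p = 1.13e-09; adjusted p = 0.308 with an estimated correlation). Basement membrane genes fell in 11 of 13 cases (11 adjusted over the list alone; median -1.63, adjusted p = 8.57e-07; adjusted p = 0.311 with an estimated correlation), and fibroblast genes in 12 of 22 (13 adjusted over the list alone; median -1.25, adjusted p = 9.77e-06; adjusted p = 0.308 with an estimated correlation). Macrophage markers fell in 7 of 15 cases (10 adjusted over the list alone; median -1.06, adjusted p = 0.00194; adjusted p = 0.502 with an estimated correlation), while epithelial markers rose in 3 of 5 (4 adjusted over the list alone; median 1.14, adjusted p = 0.00277; adjusted p = 0.246 with an estimated correlation). Ribosomal protein genes rose in 2 of 24 cases (0 adjusted over the list alone), with a median of 1.03. Camera gave an adjusted p of 0.000264 at the preset correlation and of 0.584 with an estimated correlation. Without day 50 replicate 2, 19 rose over all genes. That library is not part of this comparison, so only the shared estimate of spread changed. The median FPKM of the 24 genes was 960.1, 702.9 and 390.2 in day 60 replicates 1, 2 and 3, against 308.2 to 348.9 on day 10. CD74 rose from 531 ± 155 to 2709 ± 755 FPKM (2.35, adjusted p = 0.00109), CLDN3 rose by 3.73 (adjusted p = 2.56e-06), and GREM1 (-3.82, adjusted p = 9.41e-07), HADH (-3.10, adjusted p = 2.24e-07) and CD55 (-3.25, adjusted p = 1.57e-06) fell. In all, 3875 entries were called, 1688 rising and 2187 falling, and 2119 changed at least 2-fold.

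Genes with a curved course were read from the quadratic trend. The course of the proteoglycan gene VCAN bent upward (2.23, SE 0.31, adjusted p = 0.00282), with 17.7 ± 2.34 FPKM on day 10, 1.21 ± 0.323 on day 40 and 4.92 ± 4.62 on day 60. TBG also bent upward (2.20, adjusted p = 0.00091), as a fall from 25.2 ± 2.92 FPKM on day 10 to 4.13 on day 20 that levelled off near 0. The cholesterol exporter gene ABCA1 (chromosome 11, 60758774 to 60889795) went from 11.7 ± 1.98 FPKM on day 10 to 2.97 ± 1.20 on day 40 and 23.5 ± 8.27 on day 60 (1.96, SE 0.22, adjusted p = 0.00091; 0.0641 in the 12 libraries). The nucleotidase gene NT5E also bent upward (2.07, adjusted p = 0.00516; 0.0641 in the 12 libraries). Rises that levelled off gave negative values for TNN (-2.57, adjusted p = 0.00371) and KLK2 (-3.92, adjusted p = 0.00328; 0.0679 in the 12 libraries). The cholecystokinin receptor gene CCKAR bent downward (-2.57, adjusted p = 0.00508; 0.124 in the 12 libraries) and stood at 0.483 FPKM on day 10, 8.28 on day 30 and 0.299 on day 60.

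Of the luteal genes, CYP19A1 bent downward (-1.33, adjusted p = 0.0074), with 114 FPKM on day 10, 551 on day 30 and 395 on day 60. HSD3B also bent downward, as a fall that steepened (-1.42, SE 0.29, adjusted p = 0.0159; 0.0557 without day 60 replicate 2 and 0.308 in the 12 libraries). PTGS2 bent upward, as a fall that levelled off (1.23, adjusted p = 0.0178; 0.053 without day 10 replicate 1, 0.107 with a pseudocount of 0.1 FPKM and 0.102 in the 12 libraries). Of 20 cholesterol synthesis genes 9 bent downward and 0 upward (14 adjusted over the list alone; median -0.82, adjusted p = 8.12e-13; adjusted p = 0.246 with an estimated correlation), among them SQLE (-1.54, adjusted p = 0.00835; 0.0998 in the 12 libraries). Of 17 complement genes 5 bent upward (10 adjusted over the list alone; median 0.47, adjusted p = 3.24e-07; adjusted p = 0.22 with an estimated correlation), among them CD55 (1.65, adjusted p = 0.00091; 0.0628 in the 12 libraries). Of 30 cell cycle genes 10 bent upward (21, and 1 downward, adjusted over the list alone; median 0.43, adjusted p = 8.12e-13; adjusted p = 0.264 with an estimated correlation), and of 15 endothelial markers 5 bent downward (11 adjusted over the list alone; median -0.90, adjusted p = 6.61e-09; adjusted p = 0.264 with an estimated correlation). PTGIS (1.13, adjusted p = 0.00282), GREM1 (1.64, adjusted p = 0.00146) and FSTL3 (1.49, adjusted p = 0.0113) bent upward as falls that levelled off, and kept their calls in every setting tried. In all 607 entries were called, 252 bent upward and 355 downward, but only 17 in the 12 libraries alone, 10 upward and 7 downward. The share bent upward was 41.5%, against 32% with a pseudocount of 0.1 FPKM, 48.7% with no filter on low values and 50.1% with array weights.

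Curves of 4 further genes were lost without single libraries and in other settings. The upward bend of PTGES (0.82, adjusted p = 0.027) did not pass without day 10 replicate 3 (0.0725), day 30 replicate 3 (0.0666), day 40 replicate 1 (0.0526), day 40 replicate 2 (0.065), day 60 replicate 1 (0.0559) or day 60 replicate 3 (0.0503). The upward bend of FGG (1.97, adjusted p = 0.0421) did not pass without day 10 replicates 2 and 3 (0.119 and 0.0915), day 30 replicates 2 and 3 (0.0875 and 0.0894), day 40 replicates 1, 2 and 3 (0.0726, 0.0765 and 0.0752), day 50 replicate 3 (0.0501) or day 60 replicates 1, 2 and 3 (0.112, 0.0563 and 0.0568), each left out alone. The downward bend of OLFM3, a neuronal secreted protein gene (-2.61, adjusted p = 0.045), did not pass without day 10 replicates 1, 2 and 3 (0.0855, 0.13 and 0.0625), day 20 replicates 1 and 2 (0.0527 and 0.0534), day 30 replicates 1 and 3 (0.0855 and 0.103), day 40 replicates 2 and 3 (0.0929 and 0.0915) or day 60 replicates 1 and 2 (0.0883 and 0.126). The downward bend of KLK1 (-2.45, adjusted p = 0.0457) did not pass without day 10 replicates 1 and 2 (0.117 and 0.119), day 20 replicate 1 (0.0571), day 30 replicates 1, 2 and 3 (0.0976, 0.0714 and 0.0731), day 40 replicates 1, 2 and 3 (0.0822, 0.073 and 0.0814) or day 60 replicates 2 and 3 (0.0884 and 0.0847). In the 12 libraries the adjusted p was 0.207 for PTGES, 0.276 for FGG, 0.161 for OLFM3 and 0.238 for KLK1. With no filter on low values it was 0.0666 for FGG, 0.0702 for OLFM3 and 0.0713 for KLK1, and with a pseudocount of 0.1 FPKM it was 0.0953 for FGG and 0.066 for OLFM3.

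From day 10 to day 20 KLK2 rose from 167 ± 116 FPKM to 11680 ± 4817 (log2 change 6.30, SE 0.83, adjusted p = 0.00129). TNN (4.46, SE 0.57, adjusted p = 0.000974) and CYP19A1 (2.10, SE 0.34, adjusted p = 0.00455) rose with it. The glucosamine synthesis gene GFPT2 fell from 224 ± 42.3 to 37.8 ± 12.9 FPKM (-2.58, SE 0.32, adjusted p = 0.000763), and PTGIS (-2.09, adjusted p = 0.000304) and VCAN (-2.52, adjusted p = 0.00838) fell. CD55 (-2.25, adjusted p = 0.000671; 0.0503 in the 12 libraries), HADH (-1.43, adjusted p = 0.00208; 0.105 in the 12 libraries), TBG (-2.62, adjusted p = 0.00129; 0.0787 with only the 6 samples compared) and GREM1 (-2.41, adjusted p = 0.000671; 0.0558 with only the 6 samples compared) fell as well. The fatty acid transporter gene SLC27A2 rose (2.81, adjusted p = 0.00202; 0.0661 with only the 6 samples compared and 0.115 in the 12 libraries).

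Some of these calls were lost without a single library or in other settings. CA2 fell by 3.38 (adjusted p = 0.0108; 0.0553 without day 10 replicate 2, 0.057 without day 20 replicate 1 and 0.189 in the 12 libraries). The osteopontin gene SPP1 fell by 2.97 (adjusted p = 0.0128; 0.0593 without day 10 replicate 2, 0.0718 without day 20 replicate 2 and 0.131 in the 12 libraries). NT5E fell by 2.61 (adjusted p = 0.0128; 0.0552 without day 20 replicate 1, 0.0523 without day 20 replicate 3, 0.09 in the 12 libraries and 0.116 with only the 6 samples compared), and the class I gene DLA-79 rose by 2.70 (adjusted p = 0.0214; 0.0856 without day 10 replicate 1, 0.0916 without day 10 replicate 2, 0.0567 without day 20 replicate 2, 0.136 in the 12 libraries and 0.137 with only the 6 samples compared). IGF1 fell by 1.26 (adjusted p = 0.0173; 0.0551 without day 10 replicate 2, 0.0682 without day 20 replicate 1, 0.0709 without day 20 replicate 2, 0.223 in the 12 libraries and 0.132 with only the 6 samples compared). PTGS2 fell by 2.09 (adjusted p = 0.00913; 0.0772 with a pseudocount of 0.1 FPKM, 0.0932 in the 12 libraries and 0.109 with only the 6 samples compared). HSD3B (0.02, adjusted p = 1), CYP11A1 (-0.17, adjusted p = 0.99), SCARB1 (-0.40, adjusted p = 0.9), PTGES (-0.79, adjusted p = 0.21), HIF1A (-0.87, adjusted p = 0.145) and MKI67 (-0.63, adjusted p = 0.254) did not pass.

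By list, of 30 cell cycle genes 0 rose and 3 fell from day 10 to day 20 (18 adjusted over the list alone; median -0.54, adjusted p = 6.3e-17; adjusted p = 0.246 with an estimated correlation). Of 22 fibroblast genes 3 fell (11 adjusted over the list alone; median -0.78, adjusted p = 2.13e-09; adjusted p = 0.246 with an estimated correlation), and of 17 complement genes 5 fell (9 adjusted over the list alone; median -0.71, adjusted p = 2.23e-09; adjusted p = 0.157 with an estimated correlation). Epithelial markers rose in 1 of 5 cases (4 adjusted over the list alone; median 1.02, adjusted p = 6.87e-06; adjusted p = 0.157 with an estimated correlation). Cholesterol synthesis genes had 0 calls among 20, with a median of 0.49 (adjusted p = 0.000224; adjusted p = 0.416 with an estimated correlation). In all, 278 entries were called by limma, 82 rising and 196 falling, and 1842 had an unadjusted p under 0.05. The rising share of calls was 29.5%, against 47.2% with a pseudocount of 0.1 FPKM, 47.1% with a mean of at least 5 FPKM and 43.1% with array weights.

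From day 20 to day 30 no gene passed. CD55 (-1.18, adjusted p = 0.68), ACSL4 (-1.07) and HSD3B (-0.60, adjusted p = 1) did not pass. Cholesterol synthesis genes had a median of -0.51 (0 of 20 called, adjusted p = 8.57e-07; adjusted p = 0.311 with an estimated correlation) and autophagy genes a median of -0.16 (adjusted p = 0.00134; adjusted p = 0.308 with an estimated correlation). Of 17147 entries limma called 0, with 640 at an unadjusted p under 0.05 where 857 are expected by chance, and the lowest adjusted p was 0.65.

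From day 30 to day 40 the calls were confined to 1 locus. STAR was listed at 0 in the 3 libraries of day 30 and at 3477, 3626 and 2964 FPKM on day 40 (adjusted p = 1.13e-10). The other calls were 2 entries with the same coordinates, EIF4EBP1 of translation control (adjusted p = 0.0061), and a merged entry of ASH2L and EIF4EBP1, named here after their values were seen. Both were also listed at 0 in all 9 libraries of days 10 to 30. The neighbouring genes LSM1 (29.2 to 108 FPKM), GOT1L1 (10.4 to 17.4) and BAG4 (6.79 to 13.5) were never at 0. Cell cycle genes had a median of -0.28 (0 of 30 called, adjusted p = 8.58e-13; adjusted p = 0.264 with an estimated correlation), with TOP2A at -0.89 (adjusted p = 0.782), and macrophage markers a median of -0.46 (adjusted p = 4.44e-05; adjusted p = 0.349 with an estimated correlation). ACSL4 (-1.72, adjusted p = 0.21), HADH (-0.95, adjusted p = 0.234) and HSD3B (-1.27, adjusted p = 0.929) did not pass. Progesterone synthesis genes had a median of -0.14 and a mean of 0.91, the mean being set by STAR (adjusted p = 0.362). In all 3 entries were called, all rising, against 63.6% rising with array weights, and 672 had an unadjusted p under 0.05.

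From day 40 to day 50 some cholesterol synthesis genes fell. SQLE went from 75.3 ± 33.1 to 10.98 ± 7.54 FPKM (log2 change -2.74, SE 0.40, adjusted p = 0.0227). IDI1 (-2.24, SE 0.34, adjusted p = 0.0227) and ACLY, which makes the acetyl-CoA for lipid synthesis (-2.44, SE 0.37, adjusted p = 0.0227), fell as well. INSIG1, which holds back sterol synthesis (chromosome 16, 18260389 to 18272232; -2.78, SE 0.46, adjusted p = 0.0313), fell with DHCR7 (-2.48, SE 0.41, adjusted p = 0.0313), LSS (-2.29, SE 0.39, adjusted p = 0.0313) and FDFT1 (-2.06, SE 0.33, adjusted p = 0.0302) of the same pathway. Of 20 cholesterol synthesis genes 0 rose and 7 fell (18 adjusted over the list alone; 1 over all genes without day 50 replicate 2), with a median of -1.44 (adjusted p = 1.37e-20; adjusted p = 0.22 with an estimated correlation). Each of these calls, for SQLE, IDI1, ACLY, INSIG1, DHCR7, LSS and FDFT1, was lost without some single libraries and in other settings. Without day 40 replicate 2 the adjusted p was 0.146 for SQLE and IDI1 and 0.15 for the others. Without day 40 replicate 3 it was 0.157 for INSIG1, DHCR7 and LSS and 0.13 for the others. Without day 50 replicate 1 it was 0.0761 for SQLE, 0.0857 for IDI1 and ACLY, 0.129 for INSIG1 and LSS, 0.097 for DHCR7 and 0.108 for FDFT1. Without day 50 replicate 2 it was 0.146 for INSIG1 and 0.0998 for the other genes except DHCR7, which passed. INSIG1, DHCR7 and LSS also did not pass without day 10 replicate 1 (0.0543 each), day 10 replicate 2 (0.0525 for INSIG1 and DHCR7, 0.0548 for LSS), day 20 replicate 1 (0.0555 each), day 20 replicate 2 (0.057 for INSIG1 and DHCR7, 0.0592 for LSS), day 20 replicate 3 (0.0597 each) or day 30 replicate 1 (0.0586 for INSIG1 and DHCR7, 0.0593 for LSS). LSS did not pass without day 30 replicate 2 (0.0505) or day 40 replicate 1 (0.0619). FDFT1 did not pass without day 10 replicate 1 (0.0543), day 20 replicate 3 (0.0551) or day 30 replicate 1 (0.0586). With only the 6 samples compared the adjusted p of each was 0.813, and in the 12 libraries it was 0.226 for SQLE, 0.244 for ACLY, 0.273 for IDI1 and 0.302 for the others. With array weights it was 0.0522 for SQLE, IDI1, DHCR7 and FDFT1 and 0.0675 for ACLY, INSIG1 and LSS. With no filter on low values it was 0.0734 for INSIG1 and DHCR7, 0.0786 for LSS and 0.0565 for FDFT1, and with a pseudocount of 0.1 FPKM it was 0.0625 for LSS.

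No other gene discussed here passed from day 40 to day 50, among them ABCA1 (1.65, adjusted p = 0.0705), HSD3B (-2.14, adjusted p = 0.0766) and FABP3 (-3.38, adjusted p = 0.0506). Endothelial markers had a median of -0.94 (0 of 15 called, 10 falling adjusted over the list alone, adjusted p = 7.4e-09; adjusted p = 0.264 with an estimated correlation), with VWF at -1.44 (adjusted p = 0.234). Macrophage markers had a median of 0.91 (0 of 15 called, 9 rising adjusted over the list alone, adjusted p = 5.78e-08; adjusted p = 0.307 with an estimated correlation), with the myeloid adaptor gene TYROBP at 1.47 (adjusted p = 0.205). T and natural killer cell markers had a median of 0.96 (3 rising adjusted over the list alone, adjusted p = 7.68e-06; adjusted p = 0.308 with an estimated correlation), with CD247 at 1.35 and SKAP1 at 1.02 (adjusted p = 0.193 each). Basement membrane genes had a median of -0.91 (9 falling adjusted over the list alone, adjusted p = 2.42e-07; adjusted p = 0.308 with an estimated correlation). Ribosomal protein genes had a median of 0.82 (adjusted p = 0.000117; adjusted p = 0.566 with an estimated correlation), and without day 50 replicate 2 the median was 0.051 (adjusted p = 0.972). In all, 14 entries were called by limma, 1 rising and 13 falling, and 2013 had an unadjusted p under 0.05. The rising share of calls was 7.1%, against 22.2% with no filter on low values and 0% with a pseudocount of 0.1 FPKM or with array weights. Without day 50 replicate 3, 49 rose and 117 fell, and without day 50 replicate 1, 3 rose and 1 fell. In most other refits without a library, more calls fell than rose. The single call in the 12 libraries alone rose, as did that with only the 6 samples compared.

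From day 50 to day 60 no gene passed. HSD3B (-1.41, adjusted p = 0.47), PTGES (0.88, adjusted p = 0.47), IGF1 (-0.94, adjusted p = 0.449), CLDN3 (1.38, adjusted p = 0.449) and the small heat shock gene HSPB1 (0.82, adjusted p = 0.47) were among those that did not pass. Macrophage markers had a median of -0.52 (0 of 15 called, adjusted p = 0.000241; adjusted p = 0.404 with an estimated correlation). Angiogenic genes had a median of -0.35 (2 falling adjusted over the list alone, adjusted p = 0.000349; adjusted p = 0.308 with an estimated correlation), with EDNRB at -1.26 and the Notch ligand gene JAG1 at -0.75 (adjusted p = 0.449 each). Of 17147 entries limma called 0, with 1345 at an unadjusted p under 0.05, and the lowest adjusted p was 0.113.

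Libraries differed in sum and in ribosomal protein signal. Day 50 replicate 2 had a sum of 1259018 FPKM (493168 to 747169 in the others) and a median correlation of 0.863 with the other libraries (0.905 to 0.944 in the others). The median FPKM of 24 ribosomal protein genes was 1634.2 in this library and 291.2 to 960.1 in the others. Mitochondrial genes held 10.47% to 14.76% of the FPKM on days 10 to 30 and 5.27% to 10.76% on days 40 to 60.

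**Figure D4:**
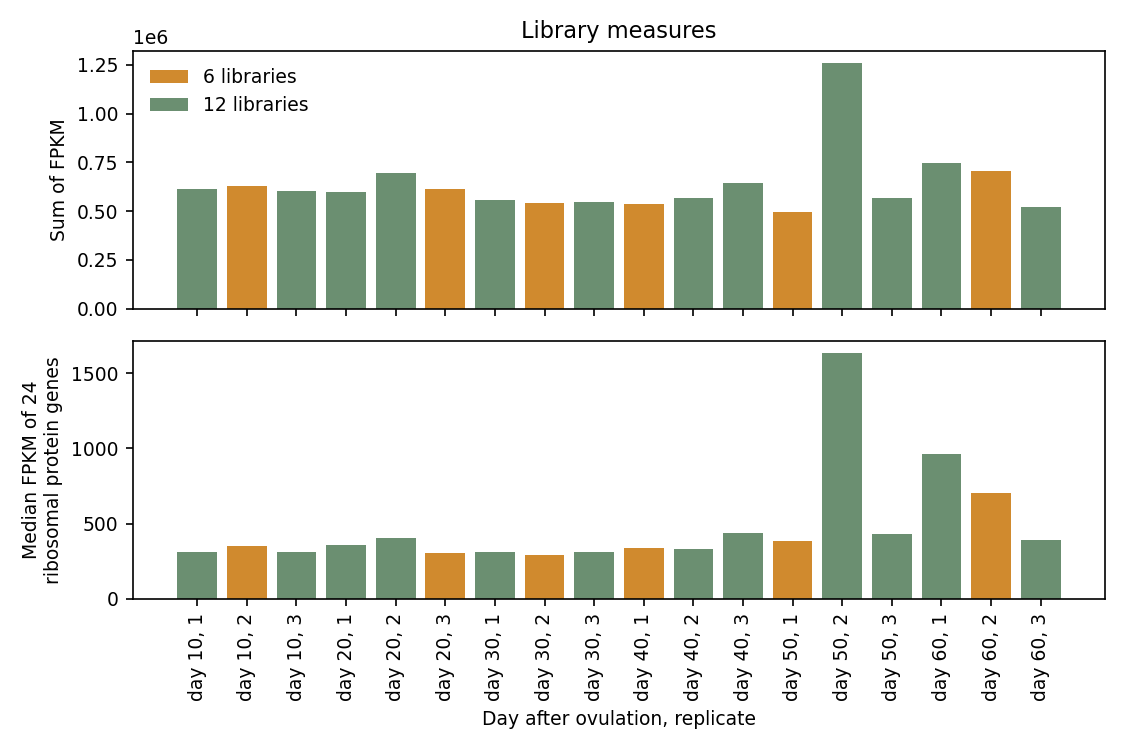
Sum of FPKM and median FPKM of 24 ribosomal protein genes in each library, coloured by the division into 6 and 12 libraries. Day 50 replicate 2 has the highest sum (1259018) and the highest median (1634.2).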

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

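Of 530 results for named genes 399 were called, and 0 of these calls turned direction in the settings tried. The refits reused the libraries from which the calls were chosen, so a turn of a call was unlikely beforehand. Results without a call did turn sign in 91 of 3879 refits, among them the linear change of INSR (-0.11, and 0.065 in the 12 libraries alone). The calls were refitted with each library left out, and 567 of 7182 refits lost the call, as did 294 of 4486 refits under other settings. The counts of calls moved more. Requiring a mean of 5 FPKM tests fewer genes and gave 1779 genes differing between days, 3236 with a linear and 341 with a quadratic trend, 2219 for day 60 against day 10, 136 for day 20 against day 10 and 26 for day 50 against day 40. Array weights gave 5249 differing between days, 2384 quadratic, 6054 for day 60 against day 10, 859 for day 20 against day 10, 44 for day 40 against day 30 and 1 for day 50 against day 40; the cause was not tested. The 12 libraries alone, a setting chosen after seeing the data with fewer samples, gave 768 differing between days, 2920 linear, 17 quadratic, 1642 for day 60 against day 10, 35 for day 20 against day 10, 2 for day 30 against day 20, 5 for day 40 against day 30, 1 for day 50 against day 40 and 1 for day 60 against day 50. With only the 6 samples compared, also fewer samples, there were 126 calls for day 20 against day 10, 1 for day 50 against day 40 and 1 for day 60 against day 50. No filter on low values gave 9 for day 50 against day 40 and 9 for day 60 against day 50, and quantile normalization 27 for day 50 against day 40; the cause was not tested. Among further settings chosen after seeing the data, summing entries of 1 symbol gave 5 for day 40 against day 30, 22 for day 50 against day 40 and 1 for day 60 against day 50, and leaving out entries listed at 0 left 1 for day 40 against day 30.

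Leaving out a library at a time gave 2123 to 3900 genes differing between days, 4337 to 6211 linear, 262 to 1213 quadratic and 2691 to 5410 for day 60 against day 10. It gave 126 to 417 for day 20 against day 10, 0 to 2 for day 30 against day 20, 2 to 7 for day 40 against day 30, 1 to 166 for day 50 against day 40 and 0 to 3 for day 60 against day 50. Without day 50 replicate 2 the counts rose to 3900 differing between days, 5933 linear, 1213 quadratic and 5410 for day 60 against day 10. Without day 50 replicates 1 and 3 they were 3363 and 3581 differing between days and 6008 and 6211 linear. They were 722 and 586 quadratic and 4092 and 4078 for day 60 against day 10. That last comparison holds no day 50 library, so its fitted changes stayed the same. Its count could move only through the estimate of spread shared by all days. For the other counts the cause was not tested. The quadratic count was 347, 270 and 381 without day 10 replicates 1, 2 and 3, 386 and 324 without day 30 replicates 1 and 3, 322 without day 40 replicate 2, and 355 and 262 without day 60 replicates 1 and 2. The count for day 20 against day 10 was 164 and 126 without day 10 replicates 1 and 2, and 158, 155 and 141 without day 20 replicates 1, 2 and 3. A term for the division into 6 and 12 libraries, chosen after seeing the data, gave 3222 differing between days, 5814 linear, 711 quadratic, 4186 for day 60 against day 10 and 309 for day 20 against day 10. Of 272 list tests camera called 101 at the preset correlation and 0 with an estimated correlation, fry called 74 and its mixed test 125; the cause was not tested. Sequencing depth is unknown, so low FPKM values could not be told from absent transcripts.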

Other observations

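The course of WT1, a transcription factor gene of the urogenital ridge, bent downward (-0.95, adjusted p = 0.0103; 0.23 in the 12 libraries), with 4.46 FPKM on day 10, 10.28 on day 20 and 4.32 on day 60. MGST1 of glutathione conjugation rose over the series (1.88, adjusted p = 0.00199), with 3.62 FPKM on day 10 and 26.1 on day 60. KLK2 varied widely between animals late in the series (12710 ± 9014 FPKM on day 50 and 11410 ± 12110 on day 60, n = 3 each), as did NT5E on day 10 (87.6 ± 79.0) and FGG on day 10 (77.3 ± 72.4).

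STAR was listed at 0 in 9 libraries and at 499.5 to 3626 FPKM in the other 9, and both tests of this pattern were chosen only after the result was seen. A failed estimate over the whole locus would put other entries at 0 in exactly the same 9 libraries while above 10 FPKM in the other 9, and the test found 1 such entry within 100 kb (the merged ASH2L and EIF4EBP1), which suggests that a failed estimate is possible. The single EIF4EBP1 entry was at 0 in the same 9 and at most 2.04 FPKM elsewhere. Processing that differed between days over many loci would give entries elsewhere with the same pattern, and the test found 0 entries outside the STAR locus, which argues against zeros placed at many loci, while processing that lowered other loci without zeroing them was not tested. A change of STAR alone would not set the merged entry to 0 in these 9 libraries, against 51.48 to 125.2 FPKM in the other 9. This argues against reading the zeros as STAR levels, and whether STAR was lower on days 10 to 30 remains open.

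The 6 libraries apart from the other 12 were seen in the values, and the batch test was chosen only after the result was seen. The division was set by which entry named SPTSSA held the larger FPKM. The first and second entry stood at 22.76 and 0.41 in day 10 replicate 1, and at 0 and 37.58 in day 10 replicate 2. By the difference of mean log2 values, the lysosomal gene PSAP was higher in the 6 (4.54), and SNRPG (-3.30), EID1 (-3.23), YPEL5 (-3.20) and CXCR4 (-2.74) were lower in the 6. For the term of the 6 libraries 260 entries passed (71 higher and 189 lower), against at most 1 in 100 other divisions, but the division was found from the values, so this leaves a library or sequencing batch open beside other causes. A variant shared by related animals that acts only on genes near it would give calls in few places. The calls lay on 41 chromosomes and scaffolds, which argues against such a local variant. Variants at many places, or 1 acting on distant genes, could also give this spread, so relatedness of the animals stays open. Reads moved between entries of 1 gene symbol would show as opposite moves. Of the passing entries with 1 symbol, 47.5% shared it with an entry moving the other way (96 of 202). This share lay just under the bound set beforehand, which counted against moved reads. After the share was seen, the bound was replaced by a binomial interval around it. No share was computed for entries that did not pass, so the value cannot decide and moved reads stay open. The SPTSSA entries, which set the division, moved in opposite ways and were left out of these tests.

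Day 50 replicate 2 lay apart from the other libraries. The trend genes of the other 17 libraries predicted day 58.5 for it, an error of 8.5 days against at most 6.3 in the others. A mislabelled day may be involved, but only ribosomal protein genes were left out of the trend genes. Other short transcripts, also raised in this library, could shift the predicted day, so the error cannot tell these apart. Few genes taking most of the signal stays open: its 100 highest entries held 55.7% of its FPKM, and without them its sum was 557296 against at most 465710 in the others, so its excess over the highest other library went from 511848 to 91586. The bound set beforehand, a sum still above the others, was met, but it was wrong because it ignored how much of the excess these entries carried. A gain of all short transcripts would raise other small proteins as much as ribosomal ones, and small oxidative phosphorylation subunits deviated by a median of 2.24 against 2.36 for ribosomal protein genes, which is in line with it. No explanation was singled out.

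The fall of cholesterol synthesis genes from day 40 to day 50 led to the hypothesis of sterol sensing. It holds that genes raised by the factor SREBP2 fall and genes raised by the sterol receptor LXR rise. The median log2 change of the synthesis list was also below 0 from day 20 to day 30 (-0.51) and from day 30 to day 40 (-0.39). From day 40 to day 50 the 6 LXR targets had a median log2 change of 0.15, with 3 above 0 and 3 below. Limma's camera gave an adjusted p of 0.698 over the 6 tests of these lists. PLTP stood at 0.49, ABCG1 at -0.05 and LPCAT3 at -0.56. In the linear trend over all days the LXR targets had a median of -0.36, with 4 below 0 and 2 above. By limma 0 of them rose over all days and LPCAT3 fell (-1.34, adjusted p = 0.000561). ABCA1, a further gene raised by LXR, was not in this list, and its positive change from day 40 to day 50 did not pass. SREBP2 targets outside the synthesis list had a median of -0.97 (limma's camera, adjusted p = 0.000187; adjusted p = 0.0633 with an estimated correlation), and 7 of 8 were below 0 with 0 called, among them FADS1 (-1.84, adjusted p = 0.126) and SCD (-1.50, adjusted p = 0.104). Over all days 6 of these 8 fell, with a median of -1.89. FADS1, FADS2, ELOVL6, FASN, SCD and ACACA are genes of fatty acid synthesis and desaturation. The others, TMEM97 and MMAB, stood at -0.42 and 0.50 from day 40 to day 50. The SREBP2 list fell at the preset correlation, but mostly through fatty acid genes, so it cannot decide whether SREBP2 was the factor. The LXR part was not shown by the 6 genes tested, and the hypothesis remains open.

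The labels of the 18 libraries were also exchanged at random over the days, with the true grouping counted among the regroupings and splits below. As many calls as with the true days came in 1 of 100 regroupings for the F test (2983 calls; 1691 in the highest other), in 1 for the linear trend (5538; 2890) and in 2 for the quadratic trend (607; 1552). The regrouping with 1552 quadratic calls placed day 50 replicate 2, day 60 replicate 1 and day 60 replicate 2 together, which suggests that it followed the structure of the samples. For pairs of days the 10 splits are too few for a share under 0.05. As many calls came in 1 of 10 splits for day 60 against day 10 (0 in the highest other), day 20 against day 10 (1 in the highest other), day 40 against day 30 (1) and day 50 against day 40 (1). For day 30 against day 20 and for day 60 against day 50 the true split gave 0 calls. All 10 splits reach that number whatever the data, so this count cannot tell anything there. The highest other split gave 0 calls for day 30 against day 20. For day 60 against day 50, the split with day 50 replicate 2, day 60 replicate 1 and day 60 replicate 2 on 1 side gave 2646 calls.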
